A study of Mus musculus with 12 samples.

How the data were processed

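Spinal cord RNA of 12 mice was measured, each on its own expression array, in 3 groups of 4 mice at an age of 13 days. Groups were taken from the labels: wildtype with vehicle, SMA with vehicle, and SMA with ceftriaxone at 200 mg/kg daily from day 5. The labels give the wildtype group a single intact mouse Smn allele and the SMA groups none, with human SMN2 transgenes in all groups. They mention both whole cords and lumbar segments and do not settle which was used for the arrays, and they do not state the sex of the mice. Tissue was perfused with fixative, and labelled cRNA was made by amplification, per the labels' protocols.

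The deposited values are MAS5 signal intensity per probe set on a linear scale, per the submitters' processing notes, and the MAS5 version is not given in the sources used here. Each array had been scaled by the authors: the mean without the top and bottom 2% of probe sets was about equal on all arrays, as tested on the deposited values. Detection calls were not used here, so no probe set could be called present or absent. The file holds 22690 probe sets, of which 20393 have 1 gene symbol in the platform annotation of 2016, 691 have several and 1606 have none. Symbols were updated through gene identifiers of the mouse reference, which matched 20364 probe sets, and no reference coordinates were used. Probe sets with several symbols or none were not named. Chat is not reported here.

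The offset 16 was added to each signal before taking log2, so fold changes understate the change of dim genes. After 64 control probe sets were removed, 22626 remained, and those whose mean log2 value over all arrays lay above the 40th percentile were kept (13575, lowest mean log2 value 7.14, a geometric mean signal of 125). Linear models with a mean per group were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, 9 residual degrees of freedom). All adjusted p-values of single genes are limma's moderated two-sided tests with Benjamini-Hochberg adjustment over the kept probe sets, with a threshold of 0.05. Smn1 lies below the filter, and its values come from the same model over all probe sets. Several probe sets of a gene were tested separately.

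Of 38 gene lists, 34 had the minimum of 5 measured genes. Lists were tested with limma's camera at a preset correlation of 0.01 over 8004 genes, with the brightest probe set per gene and adjustment over the lists, and again with an estimated correlation and with fry. The lists of Schwann cell, dorsal root ganglion, ependyma and sex-specific genes had too few measured genes and were not tested. The groups, models, lists, alternatives and the rule for naming genes were set before the data were examined. That rule took, for both main comparisons, the 10 genes of largest rise and the 10 of largest fall among probe sets past the threshold with 1 symbol and no overlap between the groups. It took 5 each way for SMA ceftriaxone against wildtype, the 4 members of smallest p in each list past its threshold, at most 2 in other lists, and always Smn1, Slc1a2, Nfe2l2, Gfap and Chat. Genes that the rule took only as members of lists that did not pass were left out of the report, except Rtp4 and Ifitm3, named for their signals. The closing section also names Cdkn1a and Plk2 of the p53 list for SMA vehicle against wildtype. Rag1, Cd3d, Xist and Eif2s3y are named outside the rule, as are the closing section's examples from the lists written later. All were chosen after their values were seen.

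The alternatives were offsets of 1 and 64, quantile normalization, median centring, no filter, a filter at the 60th percentile, no intensity trend, array quality weights, a fit of only the groups compared, the replicate number as a block, Xist signal as a covariate, the ratio of 3 prime to 5 prime Gapdh signal as a covariate, the mean of all probe sets of a gene, an estimated correlation, and leaving out each array in turn. Added after the data were seen were Xist signal as a covariate together with leaving out wildtype array 2, only arrays of low or of high Xist signal, and an estimated correlation without wildtype array 2. Lists of thymus genes, of B cell and myeloid genes, of the immature nervous system and of mature neurons were also written after the data were seen.

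The models were tested on simulated data in which 200 of 13575 probe sets were changed. In the simulation of SMA vehicle against wildtype, 31 of 67 changes of 0.5 on the log2 scale were found, 64 of 67 of size 1 and 66 of 66 of size 2, with 7 false calls. For SMA ceftriaxone against SMA vehicle the numbers were 38, 61 and 66 with 7 false calls, and for SMA ceftriaxone against wildtype 31, 63 and 66 with 10 false calls. A simulated list of 20 genes shifted by 0.5 passed camera in each comparison, and 0 of the unshifted lists did. The simulated genes varied independently of each other. The correlations estimated in the real lists ran from 0.0449 (NRF2 and antioxidant genes) to 0.898 (cell cycle). The simulation therefore does not test camera at the preset correlation for lists whose genes vary together.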

Results

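Gene expression was measured in spinal cord of 13-day-old mice of a transgenic line that models severe spinal muscular atrophy (SMA), a motor neuron disease caused by loss of the survival motor neuron protein. The arrays fall into 3 groups of 4 mice each: wildtype mice given vehicle, SMA mice given vehicle, and SMA mice given 200 mg/kg ceftriaxone daily from day 5. Ceftriaxone is a beta-lactam antibiotic known to raise expression of the glutamate transporter encoded by Slc1a2. Each value is the hybridisation signal of a probe set, and 13575 probe sets were tested. The number of arrays, 4 per group, limits the precision: the median standard error of a log2 fold change was 0.12.

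The targeted gene, Smn1, separated the genotypes. Its mean signal was 313 ± 70.1 (SD, n = 4) in wildtype, 4.23 ± 0.991 in SMA vehicle and 7.28 ± 5.85 in SMA ceftriaxone cords. It fell in SMA vehicle (limma adjusted p = 6.75e-07) and in SMA ceftriaxone cords (adjusted p = 2.07e-06) against wildtype. The signals of the SMA groups are not shown to lie above background, so the size of the fall is set by the offset added before taking log2: it was -4.00 at the offset of 16 used here, -5.90 at 1 and -2.45 at 64 in SMA vehicle cords. Between the SMA groups Smn1 did not pass (adjusted p = 0.589).

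Across the arrays, the SMA vehicle cords lay apart from both other groups. Correlations of log2 signal were 0.898 to 0.946 between SMA vehicle arrays and wildtype arrays 1, 3 and 4, and 0.977 to 0.982 between SMA ceftriaxone arrays and the same wildtype arrays. Wildtype array 2 correlated with the other wildtype arrays at 0.924 to 0.930, against 0.986 to 0.989 among those. This array carried genes of the thymus: Rag1, which recombines lymphocyte receptor genes, had a signal of 7862.5 against a mean of 24.9 in the other wildtype arrays, and the T cell receptor subunit gene Cd3d had 5575.8 against 6.17. Xist, transcribed from the inactive X chromosome of females, had a signal above 1000 in 1 wildtype, 2 SMA vehicle and 4 SMA ceftriaxone arrays. Eif2s3y, a gene of the Y chromosome, had signals of 0.3 to 5 in these arrays and 344.5 to 523.7 in all others. By both genes, all 4 SMA ceftriaxone arrays read as female. The labels used here do not give the sex of the mice.

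**Figure D1:**
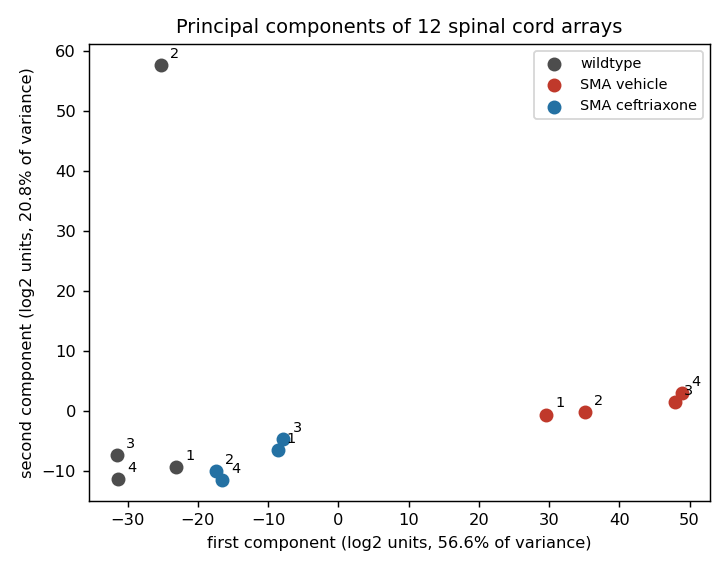
Scores of the 12 arrays on the leading principal components of log2 signal (56.6% and 20.8% of the variance, log2 units), coloured by group and numbered by replicate. SMA vehicle arrays lie between 29.6 and 48.9 on the horizontal axis, SMA ceftriaxone arrays between -17.4 and -7.81, and wildtype array 2 stands at 57.8 on the vertical axis.

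The comparison of SMA vehicle with wildtype cords asks what the disease genotype changes at this age. Genes of myelin and of the oligodendrocytes that make it fell most. Mog, a protein of the outer myelin surface, fell by 3.77 ± 0.46 (log2, SE), from a mean signal of 7221 ± 1540 to 663.9 ± 500.7 (SD, n = 4; adjusted p = 2.69e-05). Klk6, a serine protease abundant in oligodendrocytes, fell by 4.18 ± 0.34 (adjusted p = 1.54e-06), and Mal, a proteolipid of compact myelin, fell by 3.71 ± 0.40 (adjusted p = 1.17e-05). All 18 measured genes of the mature oligodendrocyte and myelin list fell, with a median log2 fold change of -2.17, and 18 fell when adjusted over the list alone. Among them, Fa2h, which hydroxylates myelin lipids, fell by 2.56 and Aspa, which breaks down N-acetylaspartate, by 2.47. The list's shift passed camera (adjusted p = 9.16e-08; adjusted p = 0.682 with an estimated correlation). The other genes of largest fall were Slc45a3 (-3.70), Ppp1r14a (-3.63), the small heat shock protein gene Cryab (-3.57), the apolipoprotein gene Apod (-3.53), the actin-binding protein gene Anln (-3.49), the connexin gene Gjb1 (-3.48) and the actin-severing protein gene Gsn (-3.32).

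Among the largest rises in SMA vehicle cords, Dcx, a microtubule-binding protein of migrating neurons, rose by 2.95 ± 0.23 (log2, SE) from 246 ± 42.0 to 2086 ± 703 (SD, n = 4; adjusted p = 1.33e-06). St8sia2, which adds polysialic acid to the neural cell adhesion molecule, rose by 2.83 ± 0.20, and the semaphorin signalling genes Dpysl3 and Crmp1 by 2.62 ± 0.17 and 2.37 ± 0.15. Cxadr, a cell adhesion molecule that also serves as a virus receptor, rose most (3.29 ± 0.19; adjusted p = 3.18e-07). Both Acta1 (2.63 ± 0.37) and Myl1 (2.51 ± 0.40), which encode skeletal muscle actin and a fast myosin light chain, rose. The rest of the 10 largest rises were the channel gene Hcn3 (2.59), the long noncoding RNA Meg3 (2.38) and the arrestin-related gene Arrdc4 (2.34).

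Lists of pan-neuronal, glutamate receptor and neurotrophic genes were higher in SMA vehicle than in wildtype cords, while those of motor neurons (camera adjusted p = 0.907) and of GABA and glycine transmission (0.522) did not pass. Of 23 measured pan-neuronal and synaptic genes, 15 rose, 3 fell and 5 did not pass, with 15 and 3 when adjusted over the list alone. The growth cone protein gene Gap43 rose by 1.99, the synaptic fusion gene Stx1a by 1.55 and the neuronal RNA-binding protein gene Elavl4 by 0.95, while Thy1, a surface protein of neurons and thymocytes, fell by 0.79. The list passed camera (adjusted p = 0.0119; adjusted p = 0.868 with an estimated correlation), but its adjusted p was 0.0815 without wildtype array 2, the array with thymus genes. Of 8 glutamate receptor genes, 6 rose and 2 did not pass, with 6 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.682 with an estimated correlation). Grik1 rose by 1.41, Grm8 by 0.97, Gria2 by 0.95 and Grik5 by 0.85. Of 19 neurotrophic factor and receptor genes, 12 rose, 3 fell and 4 did not pass, with 12 and 3 adjusted over the list alone. The examples were the neurturin receptor gene Gfra2 (2.17), the growth factor gene Igf1 (1.54), its binding protein gene Igfbp5 (1.72) and the neurotrophin receptor gene Ngfr (1.36). Camera gave that list an adjusted p = 0.0258 (adjusted p = 0.682 with an estimated correlation), and 0.0827 without wildtype array 2.

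Hox genes, which set position along the cord, were also higher in SMA vehicle cords. Of 7 measured Hox genes of lumbar to sacral levels, 6 rose, also 6 adjusted over the list alone, led by Hoxd10 (1.82), Hoxa10 (1.40), Hoxd9 (1.36) and Hoxc9 (0.77; camera adjusted p = 0.00364; adjusted p = 0.682 with an estimated correlation). Of 9 at cervical to thoracic levels, 5 rose, also 5 adjusted over the list alone, among them Hoxb3 (1.20), Hoxa7 (0.96), Hoxb2 (0.54) and Hoxb6 (0.49; camera adjusted p = 0.0355; adjusted p = 0.868 with an estimated correlation). The cervical to thoracic call ended without wildtype array 2 (0.0827), SMA vehicle array 2 (0.0521) or SMA vehicle array 3 (0.0824), with quantile normalization (0.0597) and with median centring (0.0706).

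Lists of cholesterol synthesis, vascular and microglia genes were lower in SMA vehicle cords. Of 18 cholesterol synthesis genes, 14 fell and 4 did not pass, with 14 adjusted over the list alone: the enzyme genes Idi1, Msmo1, Lss and Ebp fell by 1.21, 1.18, 1.17 and 1.10 (camera adjusted p = 2.38e-05; adjusted p = 0.682 with an estimated correlation). Of 18 endothelium and pericyte genes, 13 fell, and 16 fell when adjusted over the list alone. The pericyte gene Rgs5 fell by 1.13, the endothelial receptor genes Tek and Flt1 by 0.76 and 0.64, and the thyroid hormone transporter gene Slco1c1 by 0.72 (camera adjusted p = 0.000526; adjusted p = 0.682 with an estimated correlation). Of 21 microglia and macrophage genes, 9 fell and 12 did not pass, with 9 adjusted over the list alone, including Tmem119 (-0.83), Cd14 (-0.71), Cd68 (-0.70) and the protease gene Ctss (-0.67; camera adjusted p = 0.0161; adjusted p = 0.682 with an estimated correlation).

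Of the genes set to be named in advance, Slc1a2, Nfe2l2 and Gfap were lower in SMA vehicle cords as well. The lists of glutamate transport and metabolism (5 of 13 genes higher and 3 lower, camera adjusted p = 0.556), of NRF2 and antioxidant genes (4 of 24 higher and 12 lower, 0.155) and of astrocytes (4 of 18 higher and 8 lower, 0.177), to which these genes belong, did not pass. Slc1a2 had a mean signal of 203 ± 62.1 in wildtype and 80.9 ± 24.6 in SMA vehicle cords (SD, n = 4), a fall by 1.16 ± 0.25 on the log2 scale (adjusted p = 0.0017). Nfe2l2, the transcription factor NRF2 that drives antioxidant genes, fell by 1.64 ± 0.13, from 811 ± 106 to 251 ± 43.4 (adjusted p = 1.58e-06). Gfap, the intermediate filament of astrocytes, fell by 1.01 ± 0.20, from 8785 ± 2162 to 4395 ± 1364 (adjusted p = 0.00113), although single arrays of these groups overlapped. Chat, which marks motor neurons, was not analysed here.

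**Figure D2:**
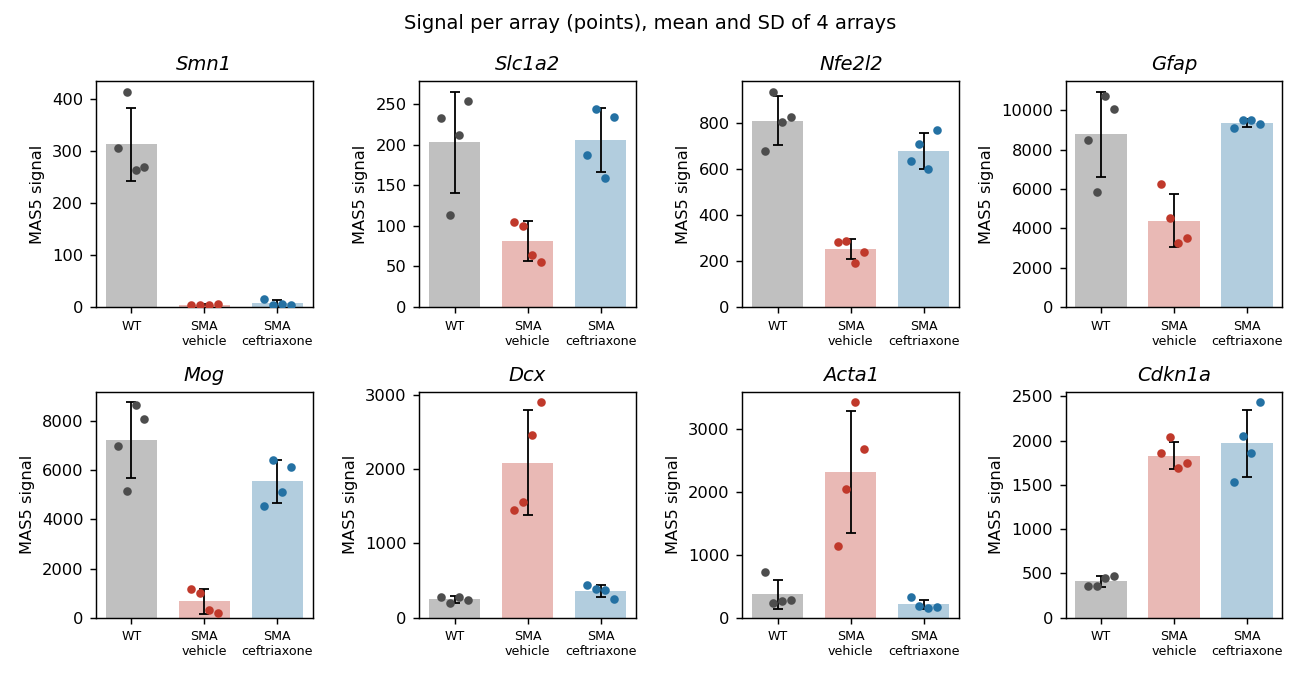
Array signal (linear units) of 8 genes in the 3 groups: points are single arrays, bars are means and whiskers are SDs of 4 arrays. Mean Mog signal was 7221 in wildtype, 663.9 in SMA vehicle and 5547 in SMA ceftriaxone cords, whereas Smn1 was 4.23 and 7.28 in the SMA groups against 313 in wildtype.

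In all, 6401 of the 13575 probe sets differed between SMA vehicle and wildtype cords, 3378 higher and 3023 lower, of which 551 and 567 changed by more than 2-fold. The 4 arrays of each group did not overlap for 42.6% of probe sets, where chance gives 2.86%. Of 34 gene lists, 5 passed camera as higher and 4 as lower, and no list passed with an estimated correlation (lowest adjusted p = 0.682); limma's fry test, which asks whether a list's genes move on balance, gave 17. Without wildtype array 2, 7932 probe sets passed, and the lists for the SMN complex (adjusted p = 0.0123, higher), cell cycle (0.0401, higher) and oxidative phosphorylation (0.00229, lower) passed as well. Median, mean and camera direction differed in sign for the motor neuron and the meninges lists, neither of which passed.

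The comparison of SMA ceftriaxone with SMA vehicle cords asks what the drug changed in the disease genotype. The myelin genes that were low in SMA vehicle cords were higher after ceftriaxone. Mog rose by 3.40 ± 0.46 (log2, SE) to a mean signal of 5547 ± 876 (SD, n = 4; adjusted p = 0.000156). Klk6 rose by 3.50 ± 0.34 (adjusted p = 3.8e-05) and Mal by 3.39 ± 0.40 (adjusted p = 8.19e-05). Of the 18 mature oligodendrocyte and myelin genes, 17 rose and 1 did not pass, and 18 rose when adjusted over the list alone, with a median of 2.05; Gsn, Fa2h and Aspa rose by 2.54, 2.24 and 2.11 (camera adjusted p = 7.05e-09; adjusted p = 0.615 with an estimated correlation). The other genes of largest rise were Ppp1r14a (3.32), Apod (3.20), Slc45a3 (3.16), Anln (2.88), Plekhh1 (2.82), Gsn by another probe set (2.81) and Gjb1 (2.77). As with their falls, the sizes of the rises of Klk6 and Slc45a3 depend on the offset.

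Slc1a2 rose by 1.21 ± 0.25 (log2, SE; adjusted p = 0.00209), from 80.9 ± 24.6 to 206 ± 39.7 (SD, n = 4), with all 4 ceftriaxone arrays above all 4 vehicle arrays. The Slc1a2 values come from a single probe set with a mean signal of 163.1, not far above the lowest geometric mean signal kept by the filter (125). Nfe2l2 rose by 1.39 ± 0.13 to 680 ± 77.0 (adjusted p = 3.8e-05). Neither the glutamate transport list (4 of 13 genes higher and 3 lower, camera adjusted p = 0.88) nor the NRF2 list (8 of 24 higher and 2 lower, 0.177) passed. Gfap rose by 1.14 ± 0.20 to 9363 ± 193 (adjusted p = 0.000906). It belongs to the astrocyte list, of whose 18 genes 13 rose, 1 fell and 4 did not pass, with 14 and 1 adjusted over the list alone (camera adjusted p = 8e-04; adjusted p = 0.615 with an estimated correlation). The connexin gene Gjb6 rose by 1.93, the neurotensin receptor gene Ntsr2 by 1.65 and the calcium-binding protein gene S100b by 1.41.

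The largest falls after ceftriaxone included 3 genes of skeletal muscle. Myl1 fell by 3.60 ± 0.40 (adjusted p = 6.32e-05), Acta1 fell by 3.31 ± 0.37 (adjusted p = 6.48e-05) and Mylpf, another myosin light chain gene, by 2.88 ± 0.43 (adjusted p = 0.000305). In ceftriaxone arrays, signals were 18.6 to 109.7 for Myl1 and 16.3 to 124.3 for Mylpf, so the sizes of their falls depend on the offset of 16. Of the 5 skeletal muscle genes measured, 4 fell and 1 rose, also adjusted over the list alone; the riser was Pvalb (1.85), a calcium-binding protein that inhibitory neurons also make. Camera gave the list an adjusted p = 0.0434 (adjusted p = 0.615 with an estimated correlation), and 0.0902 without wildtype array 2 and 0.0653 without SMA ceftriaxone array 3. Dcx fell by 2.45 ± 0.23, Cxadr by 2.40 ± 0.20 (by another probe set than above) and St8sia2 by 2.15 ± 0.20. The rest of the 10 largest falls were Jpt1 (-2.21), Meg3 (-2.12), Hcn3 (-1.96) and the vesicle GTPase gene Rab3d (-1.91).

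After ceftriaxone, the lists of pan-neuronal, glutamate receptor and neurotrophic genes were lower, while those of motor neurons (camera adjusted p = 0.204) and of GABA and glycine transmission (0.935) did not pass. Of 23 pan-neuronal and synaptic genes, 10 fell, 3 rose and 10 did not pass, also 10 and 3 adjusted over the list alone: Gap43 fell by 1.27, Stx1a by 1.08, the dendritic protein gene Map2 by 0.93 and Elavl4 by 0.55. Camera gave an adjusted p = 0.0336 (adjusted p = 0.715 with an estimated correlation), and 0.0517 with median centring. Of 8 glutamate receptor genes, 3 fell and 5 did not pass, and 4 fell when adjusted over the list alone (camera adjusted p = 0.0336; adjusted p = 0.615 with an estimated correlation). Grik1 fell by 1.11, Gria2 by 0.68 and Grm8 by 0.41, and Gria1 had -0.35 (adjusted p = 0.0573), which passed without wildtype array 2 (0.00768) or SMA vehicle array 1 (0.0366). The receptor list lost its call without SMA ceftriaxone array 1 (0.0583) and with median centring (0.0517). Grm8 lost its call without SMA vehicle array 3 (0.0743) or 4 (0.0651) or SMA ceftriaxone array 2 (0.0634). Of 19 neurotrophic genes, 9 fell, 3 rose and 7 did not pass, with 10 and 3 adjusted over the list alone. Gfra2 fell by 1.33, Igf1 by 1.13 and Ngfr by 0.98, while Fgf1, a fibroblast growth factor gene, rose by 1.18 (camera adjusted p = 0.0316; adjusted p = 0.615 with an estimated correlation).

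Of 9 Hox genes of cervical to thoracic levels, 5 fell, also 5 adjusted over the list alone (camera adjusted p = 0.0226; adjusted p = 0.629 with an estimated correlation). Hoxb3 fell by 1.09, Hoxa7 by 0.79, Hoxb5 by 0.69 and Hoxb6 by 0.40. Leaving out any SMA vehicle array, or SMA ceftriaxone array 2, 3 or 4, ended the calls of Hoxb5 (adjusted p 0.0702 to 0.131) and Hoxb6 (0.053 to 0.0989), and Hoxb5 also lost its call without wildtype array 1 (0.0569) or 3 (0.0515). Both lost it with quantile normalization (0.0821 and 0.0652) and median centring (0.0645 and 0.0622). The list of 7 Hox genes of lumbar to sacral levels, of which 4 fell, did not pass (camera adjusted p = 0.0696), but passed without SMA vehicle array 1 or 3 or SMA ceftriaxone array 3 or 4 (0.0374 to 0.0479).

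Lists that were higher after ceftriaxone besides myelin and astrocyte genes were those of cholesterol synthesis, vascular, microglia, glucocorticoid response and p53 target genes. Of 18 cholesterol synthesis genes, 12 rose and 6 did not pass, also 12 adjusted over the list alone, with Lss at 1.23, Idi1 at 0.89, Msmo1 at 0.83 and Ebp at 0.77 (camera adjusted p = 8e-04; adjusted p = 0.615 with an estimated correlation). Of 18 endothelium and pericyte genes, 10 rose, and 12 rose when adjusted over the list alone: Rgs5 by 0.88, the glucose transporter gene Slc2a1 by 0.84, Tek by 0.77 and the junction gene Esam by 0.61 (camera adjusted p = 0.00185; adjusted p = 0.615 with an estimated correlation). Of 21 microglia and macrophage genes, 7 rose and 14 did not pass, also 7 adjusted over the list alone: Tmem119 by 0.83, Ctss by 0.74, the purine receptor gene P2ry12 by 0.70 and Cd14 by 0.61 (camera adjusted p = 0.0316; adjusted p = 0.615 with an estimated correlation).

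Of 18 glucocorticoid and fasting response genes, 7 rose and 11 did not pass, and 8 rose when adjusted over the list alone. The hormone-induced genes Klf9, Sgk1, Tsc22d3 and Hif3a rose by 1.61, 1.54, 0.82 and 0.63 (camera adjusted p = 0.0336; adjusted p = 0.629 with an estimated correlation). Of 19 targets of the stress-responsive transcription factor p53, 6 rose, 1 fell and 12 did not pass, also 6 and 1 adjusted over the list alone, with Zmat3 at 1.12, Phlda3 at 0.83, Mdm2 at 0.64 and Ccng1 at 0.55 (camera adjusted p = 0.0316; adjusted p = 0.615 with an estimated correlation). Without SMA ceftriaxone array 4 the adjusted p was 0.113 for the glucocorticoid list and 0.0527 for the p53 list. Of 15 genes of the SMN complex and of the assembly of splicing particles, 4 fell and 11 did not pass, also 4 adjusted over the list alone: Gemin7 by 0.49, Phax by 0.43, Prmt5 by 0.39 and Coil by 0.36 (camera adjusted p = 0.0356; adjusted p = 0.629 with an estimated correlation). That call ended without SMA ceftriaxone array 1 (adjusted p = 0.0586) and with Xist signal, which was unevenly distributed between the groups, as a covariate (adjusted p = 0.0801).

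In all, 4879 probe sets differed between SMA ceftriaxone and SMA vehicle cords, 2482 higher and 2397 lower, of which 380 and 179 changed by more than 2-fold; with median centring the split was 1884 higher and 2535 lower. Of the 34 lists, 7 passed camera as higher and 6 as lower, none passed with an estimated correlation (lowest adjusted p = 0.615), and fry gave 21. Without wildtype array 2, 6814 probe sets passed, and the cell cycle list passed as lower (adjusted p = 0.0191). Median, mean and camera direction differed in sign for the lists of GABA and glycine transmission and of meninges, neither of which passed. High Xist signal was seen in 4 of 4 ceftriaxone and 2 of 4 vehicle arrays, and with Xist signal as a covariate Cd14 (adjusted p = 0.0525), Grm8 (0.0599), Hoxb5 (0.0977) and Hoxb6 (0.0653) lost their calls.

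**Figure D3:**
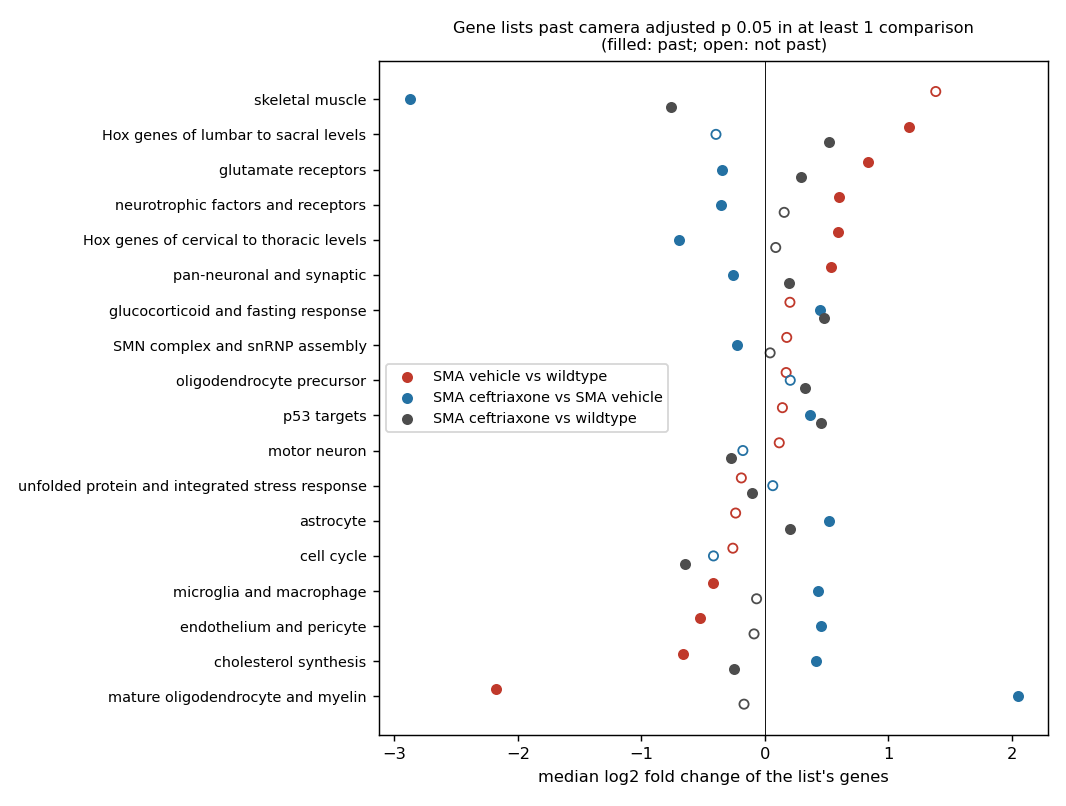
Median log2 fold change of the genes of each list (horizontal axis) that passed camera in at least 1 of 3 comparisons; filled points passed and open points did not, and each colour is a comparison. The myelin list lies at -2.17 in SMA vehicle against wildtype and at 2.05 in SMA ceftriaxone against SMA vehicle.

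Across genes, the differences of SMA ceftriaxone from SMA vehicle cords ran opposite to those of SMA vehicle from wildtype cords. Of 3023 probe sets lower in SMA vehicle than in wildtype cords, 2138 were higher in SMA ceftriaxone than in SMA vehicle cords, where independent lists would share 552.7. Of 3378 that were higher, 2148 were lower after ceftriaxone, against 596.5 for independent lists. The lists are not independent, because both comparisons use the SMA vehicle arrays. In 20 simulations with no effects at most 1 probe set had such opposite calls, but without effects few probe sets can pass at all. These simulations do not give the number that the shared arrays would produce alongside a genotype effect. The covariance of both sets of log2 fold changes over genes was -0.255 (correlation -0.908, over genes, which are not independent replicates). Since both comparisons share the SMA vehicle arrays, a negative value arises without any effect: simulated groups with no effects gave a covariance of -0.0125 and a correlation of -0.501 (100 simulations), a difference in covariance of -0.243. With the vehicle arrays divided between the comparisons, the covariance was -0.253 to -0.239 over 6 divisions. The division and the simulations deal only with error of single arrays. Anything else shared by all SMA vehicle arrays, such as dissection or cord level, would also give opposite changes and was not tested.

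**Figure D4:**
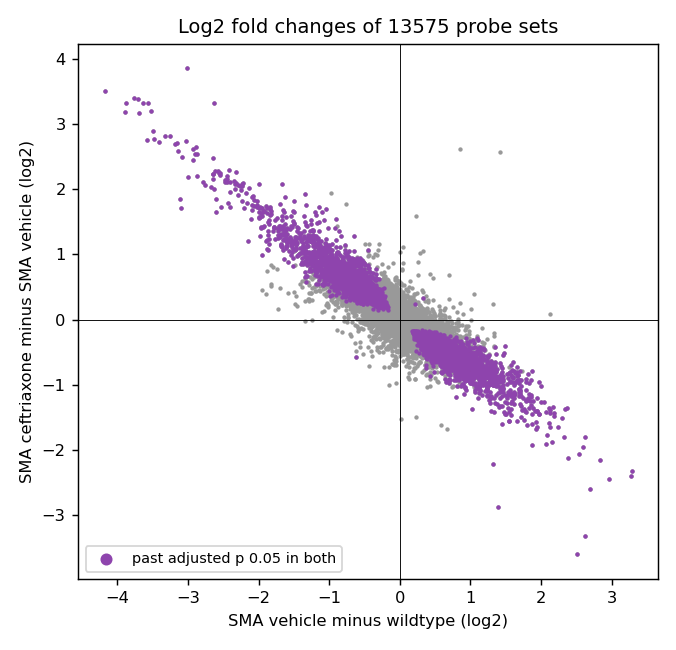
Log2 fold change of each of 13575 probe sets in SMA vehicle minus wildtype (horizontal axis) and in SMA ceftriaxone minus SMA vehicle (vertical axis), with probe sets past the threshold in both comparisons in colour. The covariance is -0.255, of which simulated groups with no effects give -0.0125.

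The comparison of SMA ceftriaxone with wildtype cords asks what differed from wildtype after treatment, whether or not it also differed in SMA vehicle cords. The cell cycle inhibitor gene Cdkn1a rose most, by 2.21 ± 0.13 (log2, SE; adjusted p = 5.78e-06), with mean signals of 410 ± 58.1 in wildtype, 1832 ± 155 in SMA vehicle and 1968 ± 377 in SMA ceftriaxone cords (SD, n = 4). It leads the p53 target list, of whose 19 genes 8 rose and 11 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 4.29e-07; adjusted p = 0.186 with an estimated correlation). The stress gene Sesn2 rose by 1.10, the kinase gene Plk2 by 0.72 and the nuclease gene Aen by 0.64. Their signals already lay above wildtype in SMA vehicle arrays, without the drug. Sesn2 had 278.6 to 407.7 there and 121.5 to 235.3 in wildtype arrays. Plk2 had 1314.7 to 1537 and 578.9 to 768.6, and Aen had 671.9 to 874 and 482.9 to 569.8, in the same order. Of the genes set to be named in advance, 3 did not pass: Slc1a2 differed by 0.06 ± 0.25 (adjusted p = 0.932), Nfe2l2 by -0.25 ± 0.13 (adjusted p = 0.343) and Gfap by 0.13 ± 0.20 (adjusted p = 0.775). Without wildtype array 2, Slc1a2 was at -0.18 and Gfap at -0.05. Slc1a2 was also below 0 without SMA ceftriaxone array 2 (-0.03) or 4 (-0.01). Of 13 genes of glutamate transport and metabolism, 1 rose, the transporter gene Slc1a3 (0.84, adjusted p = 0.0195), and 3 rose when adjusted over the list alone. That list did not pass (camera adjusted p = 0.0547), but passed without wildtype array 1, 3 or 4 or SMA vehicle array 2 and with quantile normalization (0.0215 to 0.0463).

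Other genes of largest rise were Ddit4 (1.44 ± 0.34, adjusted p = 0.0339), an inhibitor of growth signalling, and Pmaip1 (1.38 ± 0.32, adjusted p = 0.0316), a cell death gene. The sugar-metabolism gene Dcxr rose by 1.30 ± 0.24 (adjusted p = 0.0114) and the growth factor binding protein gene Igfbp3 by 1.17 ± 0.25 (adjusted p = 0.0212). Of these, Ddit4 lost its call without wildtype array 4, SMA vehicle array 2 or 3, or any ceftriaxone array (adjusted p 0.0523 to 0.0911). Pmaip1 lost it without wildtype array 1, 3 or 4 or ceftriaxone array 2, 3 or 4 (0.0503 to 0.0876), and Igfbp3 without wildtype array 3 or ceftriaxone array 2 or 4 (0.055 to 0.0643). The falls were led by Chodl, a marker of fast motor neurons (-1.27 ± 0.23, adjusted p = 0.012), and by Irak1 (-1.20), the calcitonin gene-related peptide gene Calcb (-1.16), Tesc (-1.08) and Anp32a (-1.01). Some of these differences were not seen in SMA vehicle arrays. Chodl signals were 639.8 to 1012.7 there, 543.8 to 921.9 in wildtype and 190 to 404.2 in ceftriaxone arrays. In the same order, Calcb had 444 to 892.6, 527.4 to 788.2 and 257.5 to 374.8. Dcxr had 208.2 to 433.2, 216.8 to 337.2 and 442.1 to 883.8. Irak1 passed in 1 of its 4 probe sets and Anp32a in 1 of 3. With Xist signal as a covariate, Chodl (adjusted p = 0.11), Calcb (0.104), Tesc (0.0769) and Anp32a (0.0644) lost their calls.

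Motor neuron genes were lower in SMA ceftriaxone than in wildtype cords as a list, although 2 of 11 measured genes passed, also 2 adjusted over the list alone (camera adjusted p = 0.00646; adjusted p = 0.607 with an estimated correlation). Chodl fell, and Nefh, the heavy neurofilament gene, fell by 0.66 (adjusted p = 0.0249). Nefh lost its call without ceftriaxone array 1, 2 or 3 or wildtype array 3 or 4 (0.0515 to 0.085). Prph was at -0.47 (adjusted p = 0.229) and Nefm at -0.27 (0.192), and both passed without wildtype array 2 (-0.64, 0.0481, and -0.40, 0.00733). Of 7 Hox genes of lumbar to sacral levels, 3 rose and 4 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 3.21e-05; adjusted p = 0.186 with an estimated correlation). Hoxd10 rose by 0.98, Hoxd9 by 0.84 and Hoxa10 by 0.52, and Hoxa9 was at 0.31 (adjusted p = 0.0619). Hoxd10 (0.0522 to 0.0725) and Hoxa10 (0.0878 to 0.103) lost their calls without ceftriaxone array 3 or 4 or wildtype array 3 or 4, and Hoxa10 also without ceftriaxone array 2 (0.0871).

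Of 18 glucocorticoid and fasting response genes, 6 rose and 12 did not pass, and 10 rose when adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.483 with an estimated correlation). The metallothionein gene Mt2 rose by 1.13, Klf15 by 0.94 and Errfi1 by 0.69, besides Ddit4. SMA vehicle arrays already lay above all wildtype arrays for Errfi1 (2091.4 to 2417.1 against 1229.1 to 1577.2), Klf15 (372.5 to 502.5 against 196.4 to 279.8) and Ddit4. Those of Mt2 overlapped with wildtype. Of the genes named against SMA vehicle, Klf9, Sgk1 and Tsc22d3 lay below all wildtype arrays in SMA vehicle arrays, and Hif3a overlapped. Mt2 lost its call without ceftriaxone array 2, 3 or 4, wildtype array 1 or SMA vehicle array 3 (adjusted p 0.0511 to 0.0926). Of 24 unfolded protein response genes, 2 fell, 1 rose and 21 did not pass, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.0453; adjusted p = 0.607 with an estimated correlation). Sdf2l1 fell by 0.54 and Manf by 0.29, both of the endoplasmic reticulum, Sesn2 rose, and Ppp1r15a was at 0.35 (adjusted p = 0.093). Manf lost its call without ceftriaxone array 3 or 4 or wildtype array 3 (0.0636 to 0.0751). Sdf2l1 lost it without any ceftriaxone array, wildtype array 1 or 4 or SMA vehicle array 4 (0.0511 to 0.107). The list's own call ended without wildtype array 1 (0.0597), 3 (0.128) or 4 (0.109), SMA vehicle array 4 (0.0557) or ceftriaxone array 1 (0.0828), and with median centring (0.0594).

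Of 10 oligodendrocyte precursor genes, 3 rose and 7 did not pass, also 3 adjusted over the list alone (camera adjusted p = 0.00649; adjusted p = 0.595 with an estimated correlation). The growth factor receptor gene Pdgfra rose by 0.62, the phosphatase gene Ptprz1 by 0.60 and the proteoglycan gene Cspg5 by 0.52, and Cspg4 was at 0.42 (adjusted p = 0.227). Cspg5 lost its call without ceftriaxone array 1, 2 or 3, wildtype array 3 or 4, or any SMA vehicle array (0.0597 to 0.136). Skeletal muscle genes passed camera as lower (adjusted p = 0.00646; adjusted p = 0.483 with an estimated correlation) with 0 of 5 genes past over all genes and 3 lower when adjusted over the list alone. Their values were -1.49 for Mylpf, -1.09 for Myl1, -0.76 for Pvalb and -0.69 for Acta1. Mylpf and Myl1 passed without ceftriaxone array 1 (-1.88, adjusted p = 0.0278, and -1.47, adjusted p = 0.0452), and Pvalb without wildtype array 2 (-1.04, adjusted p = 0.012).

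For 4 lists the call ended without wildtype array 2, the array with thymus genes. Of 23 cell cycle genes, 0 passed, also 0 adjusted over the list alone, while the list passed camera as lower with a median of -0.65 (adjusted p = 0.000963; adjusted p = 0.717 with an estimated correlation). Without that array the median was 0.04 (adjusted p = 0.677). Nusap1, Mki67, Ccna2 and Mcm2, all of dividing cells, were at -0.98, -0.94, -0.79 and -0.46. Of 23 pan-neuronal genes, 4 rose, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.716 with an estimated correlation), and the adjusted p was 0.634 without the array. Cplx2, Gap43, Stx1a and Elavl4 rose by 0.75, 0.73, 0.47 and 0.40. Each lost its call without ceftriaxone array 3 (0.065, 0.0573, 0.0535 and 0.0833). Cplx2 also lost it without wildtype array 3 (0.0851) or ceftriaxone array 1 (0.076) or 2 (0.0888), and Elavl4 without wildtype array 3 (0.055) or ceftriaxone array 1 (0.051). Of 18 astrocyte genes, 3 rose, and 7 rose when adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.716 with an estimated correlation), with an adjusted p of 0.295 without the array and of 0.112 with Xist signal as a covariate. Agt, the angiotensin precursor gene, rose by 1.16, the glutamate transporter gene Slc1a3 by 0.84 and Aldh1l1 by 0.61, and Sox9 was at 0.48 (adjusted p = 0.0681). Agt (0.0514 to 0.0661) and Slc1a3 (0.0505 to 0.0622) lost their calls without ceftriaxone array 2, 3 or 4.

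Of 8 glutamate receptor genes, 2 rose and 6 did not pass, and 3 rose when adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.607 with an estimated correlation), and the list had an adjusted p of 0.102 without wildtype array 2. Grik5 rose by 0.60 and Grm8 by 0.56, and Gria1 was at 0.46 and Gria2 at 0.28. Grik5 lost its call without wildtype array 4 or ceftriaxone array 1, 2 or 3 (0.0538 to 0.0813), and Grm8 without wildtype array 3 or 4 or ceftriaxone array 2, 3 or 4 (0.0525 to 0.0945). Of 18 cholesterol synthesis genes, 0 passed, also 0 adjusted over the list alone, and the list passed camera as lower (adjusted p = 0.000163; adjusted p = 0.695 with an estimated correlation). Without wildtype array 2, 11 of them fell. Dhcr7, Pmvk, Msmo1 and Ebp were at -0.41, -0.36, -0.35 and -0.33 with all arrays, and at -0.52, -0.46, -0.49 and -0.43 without it.

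In all, 572 probe sets differed between SMA ceftriaxone and wildtype cords, 446 higher and 126 lower, of which 19 and 6 changed by more than 2-fold. In SMA vehicle cords, 413 of the 446 were also higher than in wildtype, and 102 of the 126 were also lower. The count was 1434 without wildtype array 2 (854 higher and 580 lower, a more even split), 303 and 321 without wildtype array 3 or 4, and 299, 164 and 317 without ceftriaxone array 2, 3 or 4. High Xist signal was seen in 4 of 4 ceftriaxone and 1 of 4 wildtype arrays, and with Xist signal as a covariate 80 probe sets passed and 25 of the 35 named genes called here lost their calls. With wildtype array 2 left out as well, 818 passed with that covariate, 499 higher and 319 lower. Of the 34 lists, 7 passed camera as higher and 5 as lower, none passed with an estimated correlation (lowest adjusted p = 0.186), and fry gave 4. Without wildtype array 2, the lists of myelin (adjusted p = 0.00492), endothelium (0.0292) and oxidative phosphorylation (0.000287) passed as lower. With Xist signal as a covariate and all arrays, those of myelin (0.0315), endothelium (0.00471), meninges (0.00471), microglia (0.0395) and interferon response (0.000318) did. Wildtype array 3 is the only wildtype array of high Xist signal (2081.4). It was also bright for the interferon-induced genes Rtp4 (1684.1, other wildtype arrays 67.1 to 376.8) and Ifitm3 (4320.6, others 887.1 to 2098). The interferon call with that covariate therefore cannot be separated from this array. Median, mean and camera direction differed in sign for the lists of the SMN complex, SMA modifiers and SMN targets, apoptosis and autophagy, none of which passed.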

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

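The tests of thymus genes, RNA degradation, a swapped array, vascular genes and tissue maturity were chosen after the results were seen. Single arrays were compared with the other 3 of their group by the gap to the nearest array as a share of the group's range, for array measures and named genes. Of 399 such groups, 30 exceeded Dixon's critical value, which is 7.52% where chance gives about 1 in 20, and 12 of the 30 concerned wildtype array 2.

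Wildtype array 2 stood apart by its mean correlation with its own group (share 0.961, correlation 0.926), its median signal (0.842, signal 266.7) and its score on the second principal component (0.942, score 57.8). It was high for Ccna2 (0.99), Nusap1 (0.981), Mki67 (0.974), Thy1 (0.934) and Jpt1 (0.888), and low for Ntsr2 (0.978), P2ry12 (0.921), Tsc22d3 (0.849) and Ptprz1 (0.843). A swap with an SMA mouse is argued against by its Smn1 signal of 414.3, which is 26.2 times the highest of the 8 SMA arrays (15.8). Degraded RNA stays open: its log2 ratio of 3 prime to 5 prime Gapdh signal was -0.3946, above the other arrays (-0.4738 to -0.3989), while the same ratio for actin was 0.250, below the others (0.257 to 0.526). Each lay within an SD of the nearest other array (SDs of the others 0.023 and 0.0929), so neither ratio decides. Thymus tissue in the sample is a candidate explanation: the 26 measured genes of a thymus list had a median log2 excess of 5.447 over the other wildtype arrays, 25 of them above 1, and this lay above 100% of 10000 random lists, with Satb1 at 9828.6, Rag1 at 7862.5, Ccr9 at 6216.9 and Dntt at 6025.8. None of these genes is in the lists set earlier and 4 lay above the filter in the other wildtype arrays, while 16 B cell and myeloid genes (4 of them in earlier lists, 6 above the filter) had a median excess of -0.0871.

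SMA vehicle arrays stood apart from both other groups. Sex imbalance as the whole cause is argued against, since 6227 probe sets passed against wildtype and 3572 against SMA ceftriaxone with Xist signal as a covariate. Fewer myelinating cells alone would raise all other cell types alike, but the endothelium list had a median of -0.5248 where the pan-neuronal list had 0.534. By limma, 13 of 18 endothelium genes fell and 0 rose, while 15 of 23 pan-neuronal genes rose and 3 fell. SEs of the mean over genes were 0.0588 and 0.139. They treat genes as replicates and measure no spread between mice. Less mature tissue in SMA vehicle mice may underlie part of the pattern: genes of the immature nervous system exceeded those of mature neurons by 1.479 in median log2 fold change (permutation p = 0.00045, two-sided), and by 1.477 (permutation p = 0.0131) in the 13 and 9 genes left without those of earlier lists and Bcl11b. This is a hypothesis, and a difference in dissection or in cord level between groups stays open beside it. Hox genes of lumbar to sacral levels were higher in SMA vehicle than in wildtype cords (6 of 7, median log2 fold change 1.164). So were 5 of 9 of cervical to thoracic levels (median 0.5929). The cord level itself is not known, so it was not separated from maturity.

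The p53 target list passed as higher in SMA ceftriaxone than in wildtype cords, with 8 of its 19 genes higher and 11 that did not pass. Wildtype array 2 as the only cause is argued against by an adjusted p of 4.37e-09 without it, and sex imbalance by an adjusted p of 1.91e-07 with Xist signal as a covariate, both by camera at its preset correlation. With an estimated correlation the adjusted p was 0.186, so the list's call rests on the preset value. The drug alone is argued against for Cdkn1a and Plk2, which rose by 2.12 and 1.03 (log2) in SMA vehicle against wildtype cords, without it. As a list, p53 targets did not pass there (adjusted p = 0.568) and passed as higher in SMA ceftriaxone against SMA vehicle (adjusted p = 0.0316, but adjusted p = 0.615 with an estimated correlation and 0.0527 without SMA ceftriaxone array 4), so genotype and drug both stay open for the list. Its members differed. Zmat3 had 1341.4 to 1906.2 in wildtype, 709.9 to 995.8 in SMA vehicle and 1742.3 to 1977.5 in SMA ceftriaxone arrays. In the same order, Ccng1 had 1643 to 1996.6, 1575.2 to 1851.8 and 2207.7 to 2751.

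Each comparison was repeated on all 35 splits of its 8 arrays into 4 and 4. In each, only 1 split, the real one, gave as many probe sets. A share of 1 in 35 is the smallest this count can reach. The other splits mix the real groups, so any group difference widens their spread and lowers their counts. Chance division of the arrays is therefore not excluded by this count. SMA vehicle against wildtype gave 6401, with 701 as the highest of the other splits; that split exchanged wildtype array 2 for SMA vehicle array 1. SMA ceftriaxone against SMA vehicle gave 4879, with 0 as the highest other by limma. SMA ceftriaxone against wildtype gave 572, with 4 as the highest other.

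Among the remaining arrays, SMA ceftriaxone array 1 was high for the 18S probe sets at the 3 prime (0.929, signal 915) and 5 prime end (0.956, signal 388.7), and wildtype array 1 was low at the 3 prime end (0.892, signal 121.3). SMA ceftriaxone array 1 was also high for Hoxb6 (0.876) and Pdgfra (0.865), array 2 for Lss (0.966) and Msmo1 (0.872), array 3 for Jpt1 (0.947), and array 4 for Gsn (0.87) and Klf15 (0.912). SMA vehicle array 3 was high for Hoxb5 (0.94), and array 4 for Smn1 (0.857, signal 5.7). Wildtype array 1 was high for Acta1 (0.9) and Myl1 (0.872) and low for Hif3a (0.931), and wildtype array 3 was high for Ctss (0.851) and Hoxa9 (0.877) and low for Sdf2l1 (0.86).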

How the results depend on the processing

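Alternatives with arrays of low or high Xist signal, and those that combine leaving out wildtype array 2 with another change, were chosen after the results were seen. The count for SMA vehicle against wildtype stayed within 1.5 times of 6401 in 25 of 26 alternatives (5505 to 7932 without single arrays), the exception being 2253 with arrays of low Xist signal only, a fit of fewer arrays. The count for SMA ceftriaxone against SMA vehicle (4879) did so in all 26 (3528 to 7192). The count for SMA ceftriaxone against wildtype (572) did so in 13 of 25: it was 236 with median centring, 1826 with array quality weights (1107 higher and 719 lower), 111 with only the groups compared, 80 with the Xist covariate, 213 with the Gapdh ratio covariate and 164 to 1434 without single arrays (the cause was not tested). Lists past camera were 5 and 6 with the filter at the 60th percentile for SMA vehicle against wildtype and SMA ceftriaxone against SMA vehicle, which tests fewer genes, and 0 in each of the 3 comparisons with an estimated correlation, also 0 with wildtype array 2 left out too; fry gave 17, 21 and 4. The covariance of both fold changes was -0.2766 at offset 1, -0.208 at offset 64, -0.2129 with no filter, -0.2453 at the 60th percentile and -0.2904 to -0.2336 without single arrays, always below 0. The rise of Slc1a2 after ceftriaxone kept its call in all 22 alternatives (0.90 to 1.37, highest adjusted p = 0.0109), as did the fall of Smn1 in SMA vehicle cords (-5.90 to -2.45, highest adjusted p = 2.18e-05). In SMA ceftriaxone against wildtype, where neither was called, Gfap (0.13) was -0.04893 with array weights, -0.1221 with the Xist covariate and -0.05234 to 0.2373 without single arrays; Slc1a2 (0.06) was -0.179 with array weights, -0.1297 with the Gapdh ratio covariate and -0.1806 to 0.173 without single arrays, below 0 also without SMA ceftriaxone array 2 (-0.02589) or 4 (-0.007352). Of the other results for named genes, 4182 kept direction and call, 195 lost a call (32 in SMA ceftriaxone against SMA vehicle, 163 against wildtype) and 25 gained a call; leaving out single arrays ended no call of the 58 named in SMA vehicle against wildtype. The median log2 fold change of all probe sets lay within 0.1 of 0 under each scaling (furthest 0.06, with median centring). Signal over background limits dim genes: without detection calls, Smn1 signals of 4.23 and 7.28 in the SMA groups are read only as low. The single probe set of Slc1a2, with a mean signal of 163.1, is also dim.

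With the replicate number as a block, SMA ceftriaxone against wildtype had 344 probe sets past the threshold, and the other comparisons 6174 and 4572. The numbers gave no sign of pairing: correlations of deviations over 12 pairs of arrays with the same number were -0.143 to 0.133, 2 of them over 0.1, and in 3 of the 12 pairs the first array correlated best with its own number in the other group.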

Other observations

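The lists compared here were written after the results were seen. The immature nervous system list had 19 measured genes (5 of them in earlier lists) and the mature neuron list 14 (also 5). In SMA vehicle against wildtype cords, 13 immature genes rose and 1 fell, while 1 mature gene rose and 9 fell. Sox11, a transcription factor of new neurons, rose by 2.19 (log2), Dlk1 by 1.13, the tubulin gene Tubb2b by 1.10 and the fetal growth factor gene Igf2 by 1.05. The potassium channel genes Kcna1 and Kcna2 fell by 2.25 and 1.07 and the sodium channel gene Scn1a by 0.92. After ceftriaxone, 14 immature genes fell and 1 rose, and 9 mature genes rose and 1 fell, with Kcna1 at 1.99 and Scn1a at 0.77.

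A hypothesis is that SMA vehicle cords resembled younger cords. A difference in dissection or cord level between groups was not separated from it. The median of the immature list exceeded that of the mature list by 1.479 in SMA vehicle against wildtype (permutation p = 0.00045 over genes, 100000 permutations) and by 1.714 without wildtype array 2 (permutation p = 0.00057). Without the genes of earlier lists and Bcl11b, whose wildtype values had been seen, 13 immature and 9 mature genes remained, and the difference was 1.477 (permutation p = 0.0131). The difference was -1.312 in SMA ceftriaxone against SMA vehicle and 0.216 in SMA ceftriaxone against wildtype, which share arrays with the first comparison and so are no separate test. The values for SMA vehicle against wildtype are consistent with the hypothesis, but the lists were not set in advance, genes are not independent replicates and no cords of other ages were analysed here. Among the genes that passed, 2 went against it in SMA vehicle against wildtype: Slc12a2, a chloride importer of young neurons, with -1.50, and Kcnip1 of the mature list with 1.14.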
